A study of Mus musculus with 12 samples.

How the data were processed

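Bulk RNA sequencing was run on the nucleus pulposus, the gel-like core of the intervertebral disc, micro-dissected from the tail discs of 12 mice aged 12 months on a C57BL/6-129/SvEv background. Per the labels' protocols, Opa1 was deleted in adult mice at 3 months with AcanCre, a tamoxifen-activated Cre recombinase active in aggrecan-expressing cells of disc and cartilage. Tamoxifen at 100 mg/kg was given to both genotypes on 3 days in a row, and the mice were then aged for 9 more months. Each library came from 1 mouse, with 6 WT and 6 Opa1cKO libraries. Per the labels, libraries were made from 50 ng of total RNA with a stranded kit that depletes ribosomal RNA, followed by 14 PCR cycles.

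The deposited count table gives whole-number read counts for 32285 genes in each library. Per the submitters' processing notes, reads were aligned with STAR 2.7.11b to the mm10 mouse genome. The read counter, its annotation and its strand setting are not given in the sources used here, so reads shared by overlapping genes or near-identical copies cannot be traced. The authors also deposited a TPM table (length-scaled transcript share) of 32128 symbols, of which 30250 matched the count table, 14903 of them tested genes. TPM values were used only as an alternative unit. Gene positions and types were taken from the GENCODE M21 annotation of the same assembly, which matched 32235 of the 32285 gene identifiers. No column was left without a matching sample. Library totals ran from 37268242 to 56618266 counts, so a gene at 1 CPM (a count scaled by library total and TMM factor) rests on about 37 to 57 reads, and PCR copies cannot be told from independent molecules.

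Counts were tested with edgeR 4.0.16 (R 4.3.3): TMM factors, filterByExpr by genotype with a minimum count of 10, a robust quasi-likelihood fit of labelled sex plus genotype over all 12 libraries, and Benjamini-Hochberg adjustment over the 15229 genes tested. A gene was called at an adjusted p below 0.05 with no minimum fold. Labelled sex was included because it was unbalanced, with 4 females and 2 males labelled in WT against 2 females and 4 males in Opa1cKO. A genotype by labelled sex term, the genotype contrast within each labelled sex and the labelled sex term were tested in the same way. CPM values use TMM factors. Single values per library were compared by a two-sided exact permutation test, whose smallest p for 6 against 6 is 0.00216. Principal components were taken from log2 CPM with a prior count of 1.

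Before the data were examined, 41 gene lists were fixed, 27 of function and 14 of cell types or tissue handling, together with the tests, the covariates, the alternative settings and the rule for named genes. The 39 lists with 5 or more tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether a list moves one way without comparing it with other genes. Adjustment was over the lists tested. The rule named Opa1, the 12 largest rises and 12 largest falls among called genes with a mean of 1 CPM or more, the 5 smallest p, up to 4 members per function list and 3 per marker list by p, 5 genes by the interaction p and 4 by the labelled sex p. It left out predicted or unnamed genes among the rises and falls, along with Xist, Y-linked genes and immunoglobulin or T cell receptor segments, and it gave 177 distinct genes. Chosen after their values were seen, to complete small counts or describe tissue identity, were Acan, Col2a1, Col6a1, Krt19, T, Foxa1, Foxa2, Cd24a, Irf7, Hspa4l, Orai1, Hspa1a, Hspa1b, Zfp36, Fos, Txn1, Pgd, Tnfaip6, Csf1, Lif, Acadl, Cpt1b, Map1lc3b, Shmt2, Mpeg1 and Apln. These genes were not refitted with single libraries left out. Some genes that met the rule are counted but their own values are not reported here.

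The fitting steps were tested on simulated counts drawn from these libraries' means and sizes, with 200 of 15229 genes changed. For WT against Opa1cKO, edgeR recovered 43.3% of genes changed 1.5-fold, 62.7% of those changed 2-fold and 90.9% of those changed 4-fold, with 2.96% of calls false. DESeq2 gave 15.7% false calls there. For the genotype by labelled sex term, edgeR recovered 1.49%, 10.4% and 68.2% at the same folds, with 10.2% of calls false. DESeq2 was not simulated for that term or for labelled sex. Camera put 3 of 200 random lists below 0.05. Genes were drawn independently there, so that does not show how camera behaves for lists whose genes vary together. In the real lists the estimated correlation ran from -0.0483 to 0.669. Alternatives covered the sex covariate, a replicate block, DESeq2 1.42.0, limma-voom with and without quality weights, other scalings and filters, TPM with pseudocounts of 1 and 0.1, other thresholds, 1 surrogate variable (sva 3.50.0), each labelled sex alone and each library left out. Added after the data were seen were sex as sex-linked reads show it, the removal of the 4 libraries whose reads contradict their sex label, the Xist-positive libraries alone and the removal of the non-coding gene Gm26917. With those 4 libraries removed, every library labelled male is Opa1cKO. The genotype term there rests on WT 1 to 3 against Opa1cKO 5 and 6, all labelled female. In labelled males alone, both WT libraries had Xist, while Opa1cKO 1, 2 and 3 had Y-linked reads. Mitochondrial transcripts were compared with annotated nuclear transcripts with blastn 2.17.0, where a copy meant 95% identity or more over at least 100 bases.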

Results

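Gene expression was measured in the caudal nucleus pulposus of 6 WT and 6 Opa1cKO mice, 9 months after deletion of Opa1, a GTPase of the inner mitochondrial membrane that fuses inner membranes and shapes cristae. The series text asks how loss of Opa1 alters the transcriptome of this tissue. WT libraries held 45657321 to 53261644 counts and Opa1cKO libraries 37268242 to 56618266, and totals did not differ detectably between genotypes (exact permutation p = 0.502). The first principal component, with 31.6% of the variance, separated the genotypes completely (exact permutation p = 0.00216, the smallest possible), and the second, with 15.2%, did not differ between them (p = 0.935, exact permutation). No pair of libraries agreed within sampling noise, the smallest chi-square per degree of freedom between any pair being 33.3. CPM values below are means ± SD over the 6 libraries of a genotype, and log2 fold changes are Opa1cKO over WT with their standard error (SE).

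Opa1 (ENSMUSG00000038084, chromosome 16, 29579334 to 29654884, plus strand of mm10) was lower in every Opa1cKO library than in every WT library. It averaged 102 ± 17.3 CPM in WT and 40.6 ± 6.30 CPM in Opa1cKO, a log2 fold change of -1.22 (SE 0.116, edgeR adjusted p = 3.05e-05). The gene count pools deleted and undeleted exons and all cells of the sample, so it does not give the extent of recombination in the targeted cells. WT 1 to 6 had 96.11, 110.3, 107.7, 118.3, 69.26 and 107.3 CPM, and Opa1cKO 1 to 6 had 38.04, 39.01, 30.25, 42.55, 45.95 and 47.66 CPM.

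**Figure D1:**
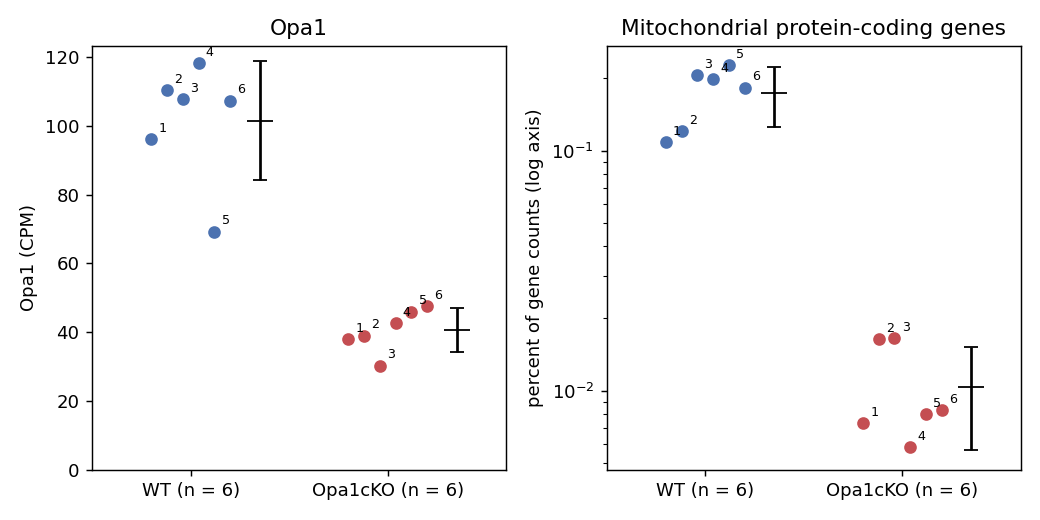
Left, Opa1 in CPM; right, percent of gene counts from the protein-coding genes of mitochondrial DNA, on a log axis. Points are libraries with their replicate number, and bars are mean ± SD of 6 libraries: Opa1 averaged 102 CPM in WT and 40.6 CPM in Opa1cKO, and the mitochondrial share 0.174% and 0.0104%.

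Loss of Opa1 lowered transcripts of mitochondrial DNA 16.7-fold as a share of counts, lowered many glycolytic and hypoxia-inducible genes and raised single genes of other pathways, such as Cpt1a (fatty acid import) and Asns (asparagine synthetase). Adrenomedullin (Adm), a vasodilator peptide induced by hypoxia, fell from 132 ± 15.9 to 16.5 ± 3.61 CPM, and the apelin receptor gene Aplnr rose from 9.17 ± 2.49 to 43.4 ± 12.9 CPM. Of 15229 genes tested, 777 were higher and 781 lower in Opa1cKO, 10.2% in all, and 263 and 259 of these changed at least 2-fold. Of the calls, 1457 were protein-coding genes. Ranges of the 2 genotypes did not overlap for 855 called genes and for 976 tested genes, or 6.41% of those tested, where chance gives 0.216%. Leaving out Opa1cKO 6 left 323 genes higher and 496 lower, and leaving out WT 6 left 463 and 510. Of the 120 called genes named by the rule, 75 passed with any 1 library left out, 42 did not pass without Opa1cKO 6, and 95 passed without WT 6. Spire1, Matn4, Has1, Mterf3, Dnajb9, Ndufb5, Egr1, Tnfrsf11a, B4galt7, Mcm5 and Cdhr4 each lost their call without any 1 of 8 to 11 of the libraries.

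Transcripts of mitochondrial DNA showed the deepest loss of any list. All 9 tested of its 13 protein-coding genes fell (9 adjusted over the list alone), with a median log2 fold change of -4.30 (camera adjusted p = 5.84e-20; adjusted p = 0.133 with an estimated correlation). Cytochrome b (mt-Cytb) went from 149 ± 44.5 to 8.003 ± 2.80 CPM, a log2 fold change of -4.30 (edgeR adjusted p = 3.39e-06). The complex I subunit gene mt-Nd6 fell by 4.64 on the log2 scale, and mt-Nd5, mt-Nd4, mt-Nd1 and mt-Nd2 fell by 3.78, 3.71, 3.64 and 3.30. Together the protein-coding genes held 0.174 ± 0.0480% of counts in WT and 0.0104 ± 0.00476% in Opa1cKO, with no overlap (SD, n = 6 each, exact permutation p = 0.00216). Most of these counts were of mt-Co1 (46454 in WT 1), while mt-Co2, mt-Co3 and mt-Atp6 had 72, 50 and 10 there, and whether mitochondrial or multi-mapping reads were removed is not given in the sources used here. The cytochrome oxidase gene mt-Co1 fell by 4.30 on the log2 scale, but all of its length has an annotated nuclear copy, so its count is uncertain, as is part of those of mt-Nd2, mt-Nd4 and mt-Nd5. mt-Nd1, mt-Nd6 and mt-Cytb have no such copy.

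Nuclear genes of the respiratory chain did not pass as lists in the full set of libraries. None of 42 tested genes of complexes II to V passed (edgeR; 0 adjusted over the list alone), and their median log2 fold change was -0.02 (camera adjusted p = 0.910). Of 37 nuclear complex I genes only Ndufb5 passed, at -0.32 (edgeR adjusted p = 0.0463; -0.25, adjusted p = 0.183, without Opa1cKO 6; 0 over the list alone; camera adjusted p = 0.674). Without the 4 libraries of contradicted sex both lists passed, direction down (camera adjusted p = 0.00786 for complex I and 0.0108 for complexes II to V). With those removed, the genotype term rests on WT 1 to 3 against Opa1cKO 5 and 6, all labelled female. Complex I also passed in labelled females (camera adjusted p = 0.0485) and in Xist-positive libraries (0.0488). Over all alternatives adjusted p ran from 0.00786 to 0.941 for complex I and from 0.0108 to 0.995 for complexes II to V. In the mitochondrial DNA maintenance list 3 of 28 genes rose and none fell (5 and 1 adjusted over the list alone): Ppargc1b, a coactivator of mitochondrial biogenesis, by 1.48, the ligase Lig3 by 0.33 and Mterf3 by 0.31. The helicase Twnk stood at -0.32 (adjusted p = 0.0633). That list's median was below 0 and its mean above (camera adjusted p = 0.772). Among fusion, fission and cristae genes 2 of 34 rose and 1 fell (2 and 1 over the list alone): the outer membrane fusion gene Mfn1 rose by 0.41 and Spire1 by 0.35, and Miga1 fell by 0.35 (camera adjusted p = 0.327). No mitochondrial chaperone or protease gene of 26 passed (camera adjusted p = 0.772). Without Opa1cKO 6 Ppargc1b was at 1.07, Lig3 at 0.25, Mterf3 at 0.27, Spire1 at 0.22 and Miga1 at -0.31 (adjusted p = 0.0543, 0.0998, 0.144, 0.230 and 0.0567).

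Glycolysis fell broadly. Of 27 tested gene entries of glycolysis and glucose transport, 14 fell and none rose (15 and 1 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 1.89e-09; adjusted p = 0.153 with an estimated correlation). The lactate exporter Slc16a3 fell from 133 ± 27.1 to 42.0 ± 7.92 CPM and Pfkfb3, which makes an activator of phosphofructokinase, from 420 ± 47.6 to 157 ± 19.2 CPM. Enolase Eno1 went from 2049 ± 293 to 937 ± 79.5 CPM, and Pdk1, which restrains pyruvate dehydrogenase, fell by 0.73 on the log2 scale (edgeR adjusted p = 0.000166). The glucose transporter Slc2a1, placed in the nucleus pulposus list, fell from 1950 ± 286 to 1078 ± 128 CPM (log2 fold change -0.78, SE 0.113, edgeR adjusted p = 0.000839).

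Hypoxia-inducible genes fell alongside. In the list of hypoxia-inducible factor, calcium and volume regulation genes 9 of 31 fell and 2 rose (13 and 6 adjusted over the list alone; camera adjusted p = 0.000810; adjusted p = 0.222 with an estimated correlation). The prolyl hydroxylase genes Egln3 and Egln1, which feed back on hypoxia-inducible factor, fell by 2.48 (SE 0.161) and 1.08 (SE 0.0763). Higd1a, a hypoxia-induced mitochondrial protein gene, fell by 1.52 and Adm by 2.95 (SE 0.146, edgeR adjusted p = 1.38e-07). Both that rose, the chaperone gene Hspa4l at 0.32 and the calcium channel gene Orai1 at 0.54, belong to the volume and calcium part. Hif1a itself rose from 293 ± 18.8 to 430 ± 46.2 CPM (log2 fold change 0.58, SE 0.0889, edgeR adjusted p = 0.00130). Gm15283, an antisense transcript over the Hif1a locus on chromosome 12, went the other way, from 38.6 ± 7.13 to 6.29 ± 0.657 CPM, and without the strand setting its reads cannot be told from those of Hif1a. Vegfa, the angiogenic factor, fell by 0.86, and the mitophagy receptor genes Bnip3 and Bnip3l by 1.05 and 0.83.

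**Figure D2:**
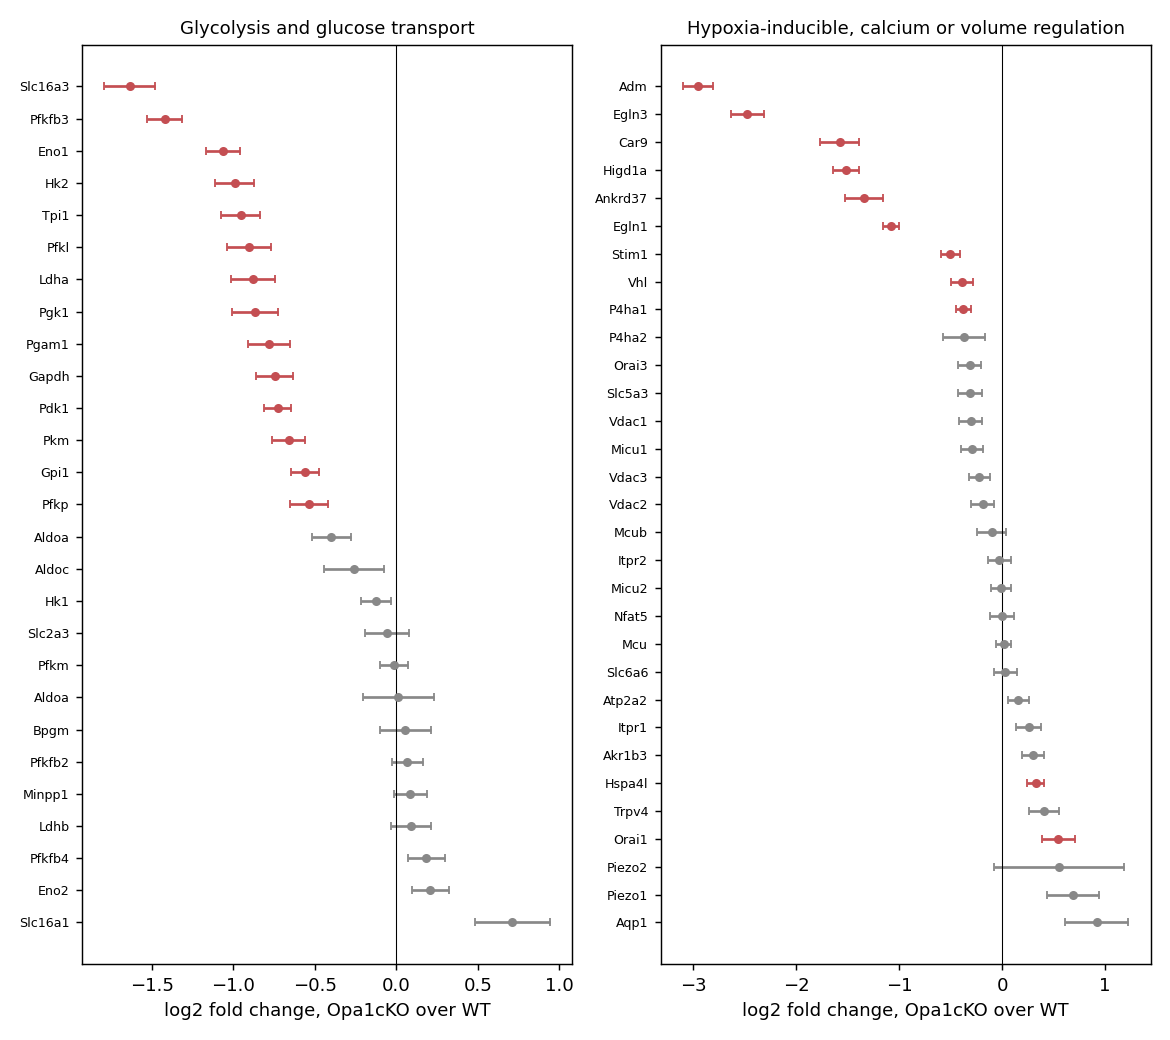
Log2 fold change (Opa1cKO over WT, x axis) of each tested member of the glycolysis list, left, and the hypoxia-inducible, calcium and volume regulation list, right; bars are SE from edgeR, and red marks an adjusted p below 0.05. Of 27 and 31 entries 14 and 9 fell, and Adm at -2.95 lies farthest from 0. Aldoa appears under 2 gene identifiers.

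In the autophagy and mitophagy list 5 of 43 fell and none rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.0257; adjusted p = 0.613 with an estimated correlation). Besides Bnip3 and Bnip3l these were Atg13 (-0.31), the mitophagy kinase gene Pink1 (-0.48) and Map1lc3b (-0.47). The list no longer passed without Opa1cKO 6 (adjusted p = 0.101) or WT 6 (0.0543), nor with sex as sex-linked reads show it (0.0621), and its adjusted p ran from 0.0113 to 0.613 over all alternatives. Without Opa1cKO 6 Pink1 was at -0.37 and Atg13 at -0.26 (adjusted p = 0.1 and 0.0571).

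Lists of other fuel genes did not pass, with calls in single genes. Of 36 fatty acid oxidation genes 5 rose and 1 fell (5 and 1 adjusted over the list alone): Cpt1a and Cpt1b, which load fatty acids for mitochondrial import, rose by 1.02 and 0.66, with Cd36 at 1.00, Ucp2 at 0.73 and Acadl at 0.66, and Acsl4 fell by 0.70. Cpt1a went from 25.3 ± 2.36 to 51.5 ± 5.00 CPM (edgeR adjusted p = 2e-05). The list as a whole did not pass, and its median was below 0 where its mean was above (camera adjusted p = 0.564). In the tricarboxylic acid cycle list 1 of 32 rose and 1 fell (the same counts over the list alone; camera adjusted p = 0.308): Pdk4, the starvation-induced brake on pyruvate dehydrogenase, rose by 0.85, and malic enzyme Me1 was at -0.41, not called without Opa1cKO 5 or Opa1cKO 6 (-0.41, adjusted p = 0.0556, without Opa1cKO 6). Scd2, a fatty acid desaturase gene, fell from 2847 ± 219 to 1518 ± 278 CPM and Srebf1, a regulator of lipid synthesis, by 0.84, the 2 calls among 30 sterol and lipid synthesis genes (2 lower over the list alone; camera adjusted p = 0.511). Srebf1 was not called without WT 6 or Opa1cKO 6 (-0.72, adjusted p = 0.0965, without Opa1cKO 6). The antioxidant list had 3 of 42 genes higher and 3 lower (4 and 7 adjusted over the list alone; camera adjusted p = 0.481): Gsta4 (1.38), Taldo1 (0.64) and Txn1 (0.51) rose, and Gstm1 (-0.65), Keap1 (-0.38) and Pgd (-0.26) fell. Taldo1 was at 0.38 without Opa1cKO 6 (adjusted p = 0.118).

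Single targets of ATF4, the transcription factor of the integrated stress response, rose. In the list of that response 9 of 36 rose and 3 fell (13 and 5 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.198). Asparagine synthetase Asns rose from 9.93 ± 1.44 to 23.3 ± 6.19 CPM and the proline synthesis gene Pycr1 from 4.55 ± 1.11 to 11.7 ± 4.55 CPM. The 3 that fell were Ddit4, an mTORC1 inhibitor that hypoxia also induces, by 2.48, the lipoprotein receptor Vldlr by 1.05 and Shmt2 by 0.67. Of 39 endoplasmic reticulum unfolded protein genes only Dnajb9 passed, at -0.32 (0 over the list alone; camera adjusted p = 0.536), and it was at -0.28 without Opa1cKO 6 (adjusted p = 0.160).

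Interferon-stimulated genes fell more often than they rose. Of 29 tested, 10 fell and 2 rose (17 and 2 adjusted over the list alone; camera adjusted p = 1.22e-05; adjusted p = 0.613 with an estimated correlation). Ifit1 fell from 12.5 ± 5.25 to 4.95 ± 1.70 CPM, the nucleic acid sensor gene Zbp1 by 2.16 and Isg20 by 0.80, and the exceptions were Ifit2 (0.37) and the regulator Irf7 (1.52). Inflammatory and secretory senescence genes went both ways, with 3 of 22 higher and 4 lower (4 and 4 over the list alone; camera adjusted p = 0.618). Igfbp5, an insulin-like growth factor binding protein gene, fell from 65.7 ± 21.2 to 8.39 ± 1.43 CPM, with the NF-kappaB inhibitors Tnfaip3 (-1.03) and Nfkbia (-0.59) and the receptor Tlr4 (-0.44), and Lif, Tnfaip6 and Csf1 rose by 1.45, 0.79 and 0.46. Of 25 cell cycle arrest genes Ccng2 fell by 1.501 and Cdkn1b by 0.61, and the p53 target Zmat3 rose by 0.50, and was at 0.45 without Opa1cKO 6 (adjusted p = 0.116; 2 and 2 over the list alone; camera adjusted p = 0.619, with its median above 0 and its mean below). Apoptosis genes had 2 of 35 higher, Apaf1 (0.64) and Bid (0.92), and Bmf lower (-0.49), the same counts over the list alone (camera adjusted p = 0.601). Without Opa1cKO 6 Bid was at 1.04 and Bmf at -0.42 (adjusted p = 0.0502 and 0.0954). The clock gene Hlf fell by 0.67, 1 of 19 clock genes (1 higher and 4 lower over the list alone; camera adjusted p = 0.118, direction down). The clock list passed, direction down, in labelled males alone (adjusted p = 0.00276) and without WT 1 (0.0439) or Opa1cKO 5 (0.0329), and ran from 0.00276 to 0.917 over all alternatives. The 28 proliferation genes as a list lay above 0 without passing (median 0.34, camera adjusted p = 0.0535, direction up) and passed, direction up, in 9 of 25 alternatives (adjusted p from 0.00616 to 0.880 over all). The only call among them was Mcm5 at -0.37 (0 over the list alone), which was at -0.34 without Opa1cKO 6 (adjusted p = 0.133).

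**Figure D3:**
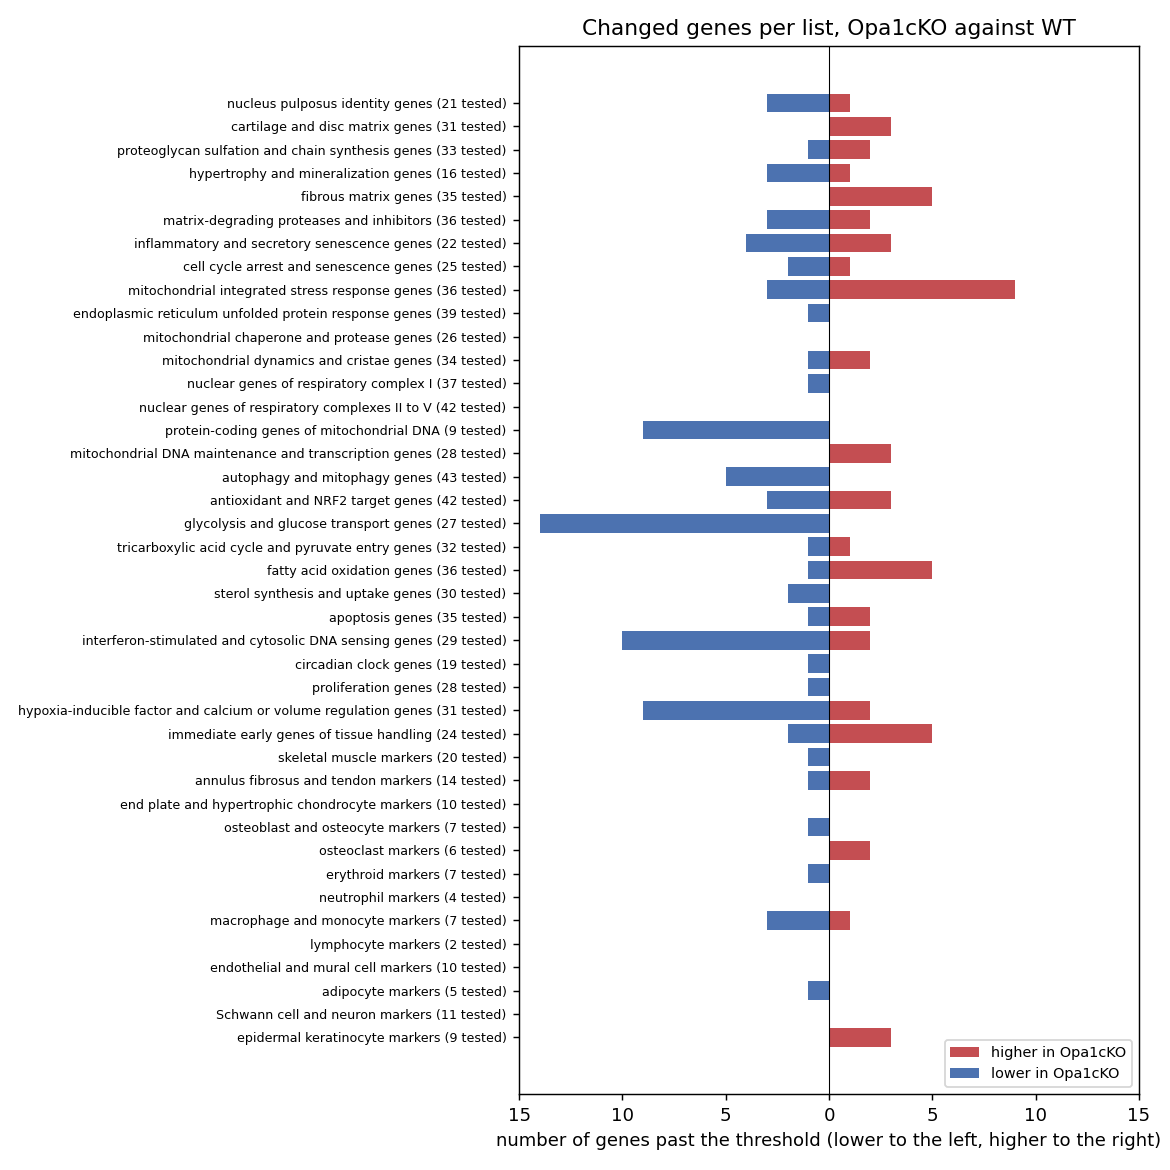
Number of genes per fixed list that were lower (left, blue) or higher (right, red) in Opa1cKO at an adjusted p below 0.05, with the number tested after each name. Glycolysis (14 lower), interferon (10), mitochondrial DNA (9) and the hypoxia-inducible, calcium and volume regulation list (9) have the most on the left, and the integrated stress response (9 higher) the most on the right.

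Most nucleus pulposus identity genes did not pass. Among 21 nucleus pulposus identity genes 3 fell and 1 rose (3 and 1 over the list alone; camera adjusted p = 0.389, median above 0 and test below): Slc2a1, Sema3c (-0.69) and the cadherin gene Cdh2 (-0.43) fell, and Hif1a rose. Cdh2 was not called without WT 6 (adjusted p = 0.0621). The notochord factor brachyury (T) was at 2719 ± 245 CPM in WT and 2882 ± 274 in Opa1cKO, and Krt19 at 2097 ± 456 and 2095 ± 570. The notochord factors Foxa2 and Foxa1 and the surface marker Cd24a were at -1.08, -0.40 and -0.34 and did not pass (adjusted p = 0.106, 0.256 and 0.154). The aggrecan gene Acan was at 13062 ± 2325 and 8628 ± 2968 CPM, which did not pass (log2 fold change -0.53, SE 0.197, edgeR adjusted p = 0.103).

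Fibrous matrix genes had 5 of 35 higher and none lower (8 and 1 adjusted over the list alone; camera adjusted p = 0.0119; adjusted p = 0.880 with an estimated correlation). Fibronectin Fn1 went from 9025 ± 1858 to 20109 ± 11239 CPM, with Col12a1 up by 1.28, Ccn1 by 1.02, Col6a1 by 0.96 and Tgfb1 by 0.82. Cartilage and disc matrix genes had 3 of 31 higher, Bgn (1.42), Chadl (1.18) and Matn4 (3.59), and none lower (the same counts over the list alone; camera adjusted p = 0.0127; adjusted p = 0.880 with an estimated correlation). Col2a1 was at 1.14 (adjusted p = 0.109). Neither list passed without Opa1cKO 6 (camera adjusted p = 0.321 for fibrous and 0.513 for cartilage matrix), and 35 and 36 of 100 splits of the 12 libraries gave a camera p as small. Without Opa1cKO 6 Fn1 was at 0.66 and Tgfb1 at 0.53 (adjusted p = 0.0652 and 0.128), while Chadl (1.17) and Matn4 (3.29) kept most of their fold without passing (adjusted p = 0.0791 and 0.132). Bgn and Col12a1 still passed, at 0.89 and 1.07 (adjusted p = 0.0450 and 0.0178). Ccn1 was not called without WT 5 or Opa1cKO 5 (adjusted p up to 0.0648).

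Of 36 proteases and inhibitors 2 rose and 3 fell (4 and 4 over the list alone; camera adjusted p = 0.647): the metalloprotease inhibitor gene Timp1 was among those that rose, by 2.78, and Htra3 (-0.93), Htra1 (-0.62) and Adam9 (-0.35) fell. Chst15 (1.80) and B4galt7 (0.65) rose and Has1 (-1.54) fell among 33 chondroitin and chain synthesis genes (the same counts over the list alone; camera adjusted p = 0.647). In the mineralization list of 16, 3 fell, among them Dlx5 (-2.21) and Vegfa (-0.86), and the pyrophosphate transporter Ank (0.90) rose (the same counts over the list alone; camera adjusted p = 0.506). Without Opa1cKO 6 Timp1 was at 1.215, Adam9 at -0.30, Chst15 at 1.24, B4galt7 at 0.31, Has1 at -1.503 and Ank at 0.53 (adjusted p = 0.229, 0.105, 0.193, 0.211, 0.137 and 0.0681).

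The largest rises leaned on 1 library. Hmga2, a chromatin protein gene of growing tissue, rose by 5.34 on the log2 scale (edgeR adjusted p = 0.00672) and was at 2.58 without Opa1cKO 6 (adjusted p = 0.0643). Moxd1 rose by 3.49 and was still called without it, at 2.22. Nkd2 (4.30), Crabp2 (2.99), Scube3 (2.80) and Gda (2.60) were not called without it, at 1.41, 1.75, 2.41 and 1.98 (adjusted p = 0.454, 0.217, 0.0941 and 0.185). Arc, an activity-induced gene, rose by 3.20 and Pirt, a regulator of sensory ion channels, by 2.88, both called with any library left out, as was Aplnr at 2.48 (edgeR adjusted p = 1.25e-06). Falls were steadier. Besides mitochondrial genes they were Sez6l (-6.26), the macrophage scavenger receptor gene Cd163 (-3.98), the keratin gene Krt2 (-3.80), the angiopoietin gene Angpt1 (-3.61) and the zinc finger gene Zbtb8b, which went from 55.9 ± 14.1 to 4.39 ± 1.18 CPM. Each of these was called with any library left out.

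Markers of other cells and of handling moved as well. Immediate early genes, which respond within minutes to dissection, had 5 of 24 higher and 2 lower (11 and 2 adjusted over the list alone; camera adjusted p = 0.00943; adjusted p = 0.880 with an estimated correlation). Egr1 (2.04), Dusp1 (1.55), Zfp36 (1.55), Hspa1a (1.58) and Hspa1b (0.71) rose, Ier3 (-1.40) and Nr4a3 (-1.86) fell, and Fos was at 597 ± 735 and 2428 ± 1354 CPM (adjusted p = 0.0572). That list was not called without WT 5 (adjusted p = 0.0590) or Opa1cKO 5 (0.0963), and 39 of 100 splits gave a camera p as small. Without Opa1cKO 6 Egr1 (1.99) and Dusp1 (1.555) kept their fold but did not pass (adjusted p = 0.122 and 0.0561).

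Of 7 tested macrophage markers Cd163, Csf1r (-0.88) and Mpeg1 (-0.97) fell and Cd68 rose from 15.3 ± 2.97 to 38.6 ± 6.51 CPM (the same over the list alone; camera adjusted p = 0.118, direction down). The list passed with fry (adjusted p = 0.0136) and in labelled males alone (0.0490), from 0.0136 to 0.847 over all alternatives. Keratinocyte markers had 3 of 9 higher (5 over the list alone; camera adjusted p = 0.0624, direction up): Dmkn (1.00), Sbsn (0.80) and Krtdap (1.52). That list passed with fry (adjusted p = 0.00328), without Opa1cKO 1 (0.0392) or Opa1cKO 6 (0.0317) and in Xist-positive libraries (0.0367), from 0.00328 to 0.328 over all alternatives. Sbsn was not called without WT 6 or Opa1cKO 6 (0.65, adjusted p = 0.106, without Opa1cKO 6), nor Krtdap without WT 5, WT 6 or Opa1cKO 5 (adjusted p up to 0.0931). The keratin gene Krt2, outside that list, went the other way, at -3.80 (edgeR adjusted p = 0.00647). Annulus and tendon markers had 2 of 14 higher, Egr1 and Adamtsl2 (1.72), and Igfbp6 lower (-0.86; 3 and 1 over the list alone; camera adjusted p = 0.178), and without Opa1cKO 6 Adamtsl2 was at 1.035 and Igfbp6 at -0.74 (adjusted p = 0.119 and 0.0682). Among 6 osteoclast markers Atp6v0d2 (3.98) and Tnfrsf11a (0.92) rose (the same over the list alone; camera adjusted p = 0.168). Without Opa1cKO 6 Atp6v0d2 was down to 2.28 and Tnfrsf11a at 1.06 (adjusted p = 0.0642 and 0.0711). A single gene fell in each of 4 further lists: Phex (-1.47) of 7 osteoblast markers, Tfrc (-0.57) of 7 erythroid markers, Lpl (-0.94) of 5 adipocyte markers and Tpm2 (-0.39) of 20 skeletal muscle markers (camera adjusted p = 0.183, 0.926, 0.952 and 0.730). Over each list alone the counts lower were 1, 1, 1 and 0, with 1 adipocyte marker higher. Median and test differed in sign for the erythroid and muscle lists. Without Opa1cKO 6 Lpl was at -0.77 and Tpm2 at -0.35 (adjusted p = 0.0542 and 0.114). No member passed in edgeR among 10 end plate, 10 vessel or 11 nerve markers (camera adjusted p = 0.647, 0.630 and 0.730), nor among 4 neutrophil and 2 lymphocyte markers, which were too few for a list test.

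By fry, 9 lists passed. Glycolysis (adjusted p = 7.86e-05), hypoxia-inducible, calcium and volume regulation (5.23e-05), mitochondrial DNA (2.47e-05), autophagy (0.0360), interferon (0.0471) and macrophage genes (0.0136) went down, and keratinocyte markers (0.00328), osteoclast markers (0.0452) and fusion, fission and cristae genes (0.0460) went up. Cartilage matrix, fibrous matrix and immediate early genes did not pass by fry (0.379, 0.369 and 0.375).

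Comparisons by sex rest on labels that the reads contradict in 4 libraries. WT 4, labelled female, had 327 CPM of Y-linked reads, and WT 5, WT 6 and Opa1cKO 4, labelled male, had Xist, the X-inactivation RNA of females, at 4183, 4382 and 4397 CPM. In the libraries labelled female 356 genes were higher and 274 lower in Opa1cKO, and in those labelled male 79 and 224. Both WT libraries labelled male, WT 5 and WT 6, had Xist, while Opa1cKO 1, 2 and 3 had Y-linked reads. In the labelled male contrast genotype is therefore confounded in part with sex as read. No gene differed between the labelled sexes in its response (edgeR; 899 at an unadjusted p below 0.05, and 9 calls by DESeq2), with Itga10 nearest at an adjusted p of 0.797. None differed between libraries labelled male and female (edgeR; 586 unadjusted, 6 by DESeq2), with the smallest adjusted p, 0.408, at Gas7. With sex taken from the reads, 6 genes differed: Xist, Kdm5c, Kdm6a, Eif2s3x and 5530601H04Rik on the X chromosome, all higher with Xist, and Ngfr on chromosome 11, higher without. Y-linked genes are not among them because too few libraries held their reads to pass the expression filter. Summed, they stood at 219 to 327 CPM in libraries without Xist and at most 0.0868 CPM in the others. Leaving out WT 1, WT 2, WT 3, Opa1cKO 1, Opa1cKO 5 or Opa1cKO 6 moved the 630 calls of the labelled females to 212, 261, 395, 406, 1298 and 81. Leaving out WT 5, WT 6, Opa1cKO 1, Opa1cKO 2, Opa1cKO 4, Opa1cKO 5 or Opa1cKO 6 moved the 303 of the labelled males to 69, 92, 132, 194, 198, 544 and 540.

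**Figure D4:**
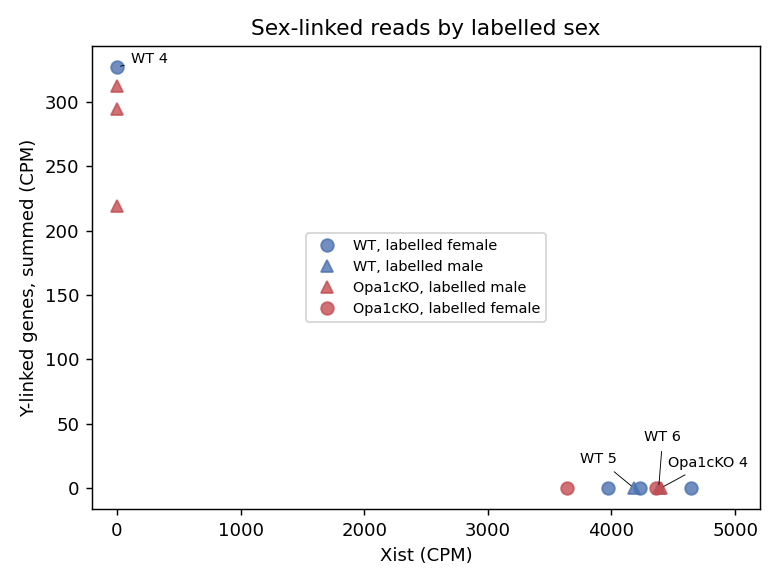
Xist (x axis, CPM) against summed Y-linked genes (y axis, CPM) in each library, with colour for genotype and shape for labelled sex. The 4 named libraries lie with the other sex: WT 4 at 327 CPM of Y-linked reads, and WT 5, WT 6 and Opa1cKO 4 at 4183, 4382 and 4397 CPM of Xist.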

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

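The tests on mitochondrial transcripts, on library scaling and on sex-linked reads were chosen only after those results were seen; the other tests were set beforehand.

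Transcripts of mitochondrial DNA were 16.7-fold lower in Opa1cKO as a share of counts while nuclear genes of the same complexes lay near 0. Whether mitochondrial or multi-mapping reads were removed before counting is not given in the sources used here, so that fold covers only the reads that remain. Sharing of reads with nuclear copies is argued against as the cause, since the 3 tested genes without an annotated copy had a median log2 fold change of -4.30 against -4.30 for all 9. Loss of cells or RNA rich in mitochondrial transcripts of both genomes is argued against by the nuclear genes of complexes II to V. Their median was -0.0168 (SE over genes 0.0193, 42 genes). That SE does not measure spread over mice, as these genes vary together (estimated correlation 0.486). However, the list passed, direction down, without the 4 libraries of contradicted sex (camera adjusted p = 0.0108, and 0.0108 to 0.995 over all alternatives). The genotype term of that setting rests on WT 1 to 3 against Opa1cKO 5 and 6. Whether transcription of 1 strand fell more cannot be told apart from equal loss: mt-Nd6, the light-strand gene, differed from the median of the heavy-strand genes by -0.60, and the strand setting of the counts is unknown. Fewer mitochondrial genomes or less transcription of both strands after loss of Opa1 remains a hypothesis, as no measure of mitochondrial DNA itself was analysed here.

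Hypoxia-inducible and glycolytic genes fell while Hif1a rose. Library scaling, which moves all genes alike, is argued against. The glycolysis median lay -0.53 (SE over genes 0.108) from that of other genes of similar abundance. GC content and gene length are argued against as well, since that median was -0.59 after their trends were removed. A smaller share of nucleus pulposus cells is argued against by 11 of their markers, chosen as not being hypoxia targets. Their median was 0.0791 (SE over genes 0.154), above a bound of -0.27 that a rule set beforehand took from the glycolysis median. Of the 11, Foxa2 (-1.08), Foxa1 (-0.40) and Cd24a (-0.34) lay past that bound without passing, and all others lay above it. In 31 hypoxia-inducible factor targets outside the fixed lists, written down before their values were seen, camera gave p = 2.34e-14, direction down (p = 3.53e-05 with an estimated correlation), and 2 of 100 splits, the real one included, gave a p as small (1.86e-14 in the other). These targets were read in the same 12 libraries, so their fall extends the pattern to more genes and does not tell its cause. Lower activity of hypoxia-inducible factor in Opa1cKO discs, for example through more oxygen left by weaker respiration, remains a candidate explanation. Oxygen and protein levels were not measured here.

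Reads of sex-linked genes contradicted the sex label in 4 libraries: Y-linked reads of 327 CPM in WT 4, and Xist of 4183 CPM in WT 5, 4382 CPM in WT 6 and 4397 CPM in Opa1cKO 4. Mixed libraries are argued against, as the lower of Xist and Y-linked reads never exceeded 0.0286% of the level in libraries that express them. Exchange between genotypes is argued against by Opa1, whose highest Opa1cKO library lay at 68.8% of the lowest WT library. Exchange within a genotype alone is argued against because the number of Y-positive libraries differed from the number labelled male in 2 of 2 genotypes, 1 against 2 in WT and 3 against 4 in Opa1cKO. Wrong entries of sex, or exchange with mice outside the series, stay open and untested.

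A screen of 132 groups of 6 values looked for 1 library that stood apart. It included the largest rises and falls, and picking genes by fold favours those with 1 extreme library. Its count is therefore a description and not a test. It found 15 such groups, where independent and normally distributed values would give about 6.6, and 8 of the 15 were in Opa1cKO 6. Among these, that library was highest of its genotype for Hmga2 (22.2 CPM, the others averaging 1.04), Nkd2 (11.4 CPM), Moxd1 (22.4 CPM), Crabp2 (21.2 CPM), Timp1 (59.6 CPM, others 5.52) and Sez6l (0.445 CPM), and for the mean log2 CPM of fibrous matrix genes (6.10, others 5.02). WT 6 was highest of its genotype for Arc (2.57 CPM). WT 1 was highest for the mean log2 CPM of fatty acid oxidation genes (5.05) and of adipocyte markers (6.14), and WT 2 lowest for integrated stress response genes (4.40). Opa1cKO 3 was highest for tricarboxylic acid cycle genes (6.14), and Opa1cKO 5, the library of lowest depth, had the fewest genes with 10 or more counts (14902).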

How the results depend on the processing

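The settings that use sex-linked reads or leave out Gm26917 were chosen only after the data were seen. Opa1 passed under all 31 alternatives, with log2 fold changes of -1.33 to -1.09 and adjusted p of 7.23e-18 to 0.0172. No call among the named genes changed direction under any alternative, and genes called both in the reported fit and in an alternative had the same sign in every one. No scaling moved the share of higher calls (49.9%) by more than 10 points or the median of all genes by more than 0.1.

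The 777 genes higher became 1222 with DESeq2, 437 with TPM and no filter, 228 at an adjusted p below 0.01, 1302 below 0.1 and 263 at 2-fold or more. The 781 lower became 326 below 0.01 and 259 at 2-fold or more. Subsets gave 167 higher and 133 lower in labelled females alone, 161 and 258 in labelled males alone, 188 and 137 without the 4 libraries of contradicting sex, and 561 and 546 in Xist-positive libraries. Without those 4 libraries the genotype term rests on WT 1 to 3 against Opa1cKO 5 and 6, all labelled female. With 1 library left out, calls ranged from 323 to 1002 higher and from 496 to 1008 lower.

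The replicate number as a block gave 351 higher and 418 lower, and kept 82 of 120 called named genes and all 8 lists. The numbers do not pair the samples: deviations of same-numbered libraries correlated at -0.217 to 0.0430. For 0 of the 6 WT libraries was the best match the Opa1cKO library of its own number.

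Interaction calls (0) became 9 with DESeq2 and ran from 0 to 22 with 1 library left out. The labelled female contrast (630) became 1489 with DESeq2 and ran from 81 to 1298, and the labelled male contrast (303) became 766 and ran from 69 to 544. Labelled sex (0) gave 6 with DESeq2, 1 without a filter, 6 with sex as read, and 0 to 2 with 1 library left out. For these and the other changed counts the cause was not tested.

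The 8 lists past the threshold became 0 with an estimated correlation and 13 in labelled females alone. Labelled males alone lost cartilage matrix (adjusted p = 0.0928), fibrous matrix (0.106), autophagy (0.0746) and immediate early genes (0.724). Both WT libraries labelled male had Xist, so in every result for labelled males genotype is confounded in part with sex as read. Skeletal muscle markers changed direction and passed in labelled females alone (0.0299, up), and passed downward in labelled males alone (0.0313). Other lists gained a call in labelled males alone (mineralization 0.0313, down; tricarboxylic acid cycle 0.0368, up), in labelled females alone (antioxidant 0.0460, down; annulus and tendon 0.0485, up) or without the 4 libraries of contradicting sex (antioxidant 0.0215, down). In 59 further cases a list that passed in neither changed sign. Depth limits low genes: folds of genes near 1 CPM rest on few reads.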

Other observations

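The genes named here and the tests of single lists by splits were chosen only after the data were seen; the target list, the counts of splits and the tests of neighbouring genes were set beforehand.

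Of 31 tested hypoxia-inducible factor targets outside the fixed lists 15 fell, none rose and 16 did not pass in edgeR (19 lower and 1 higher adjusted over the list alone). Ndrg1, a stress-response gene, fell from 1083 ± 121 to 438 ± 66.2 CPM, and Gys1 (glycogen synthase), Gbe1 (branching enzyme), Ppp1r3b and Ppp1r3c (glycogen-targeting subunits) fell by 0.79, 0.70, 0.90 and 0.73. Pgm1 (-0.34) and Pgm2 (0.07) of the same list did not pass (adjusted p = 0.124 and 0.736). Selenbp1 (-1.31) and Fam162a (-1.19) also fell. Apln, the ligand of the apelin receptor, fell from 3.48 ± 0.977 to 0.460 ± 0.250 CPM (log2 fold change -2.84, SE 0.345, edgeR adjusted p = 0.000230) while its receptor Aplnr rose by 2.48.

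Among 100 drawn of the 462 splits of the 12 libraries into 6 and 6, the real genotype split alone gave as many calls (1 of 100). It gave 1558 against 93 in the highest other. No smaller result than 1 of 100 was possible. In the other splits the genotype difference adds to the spread within groups, which can lower their counts. Chance is not excluded for the number of lists past the threshold, as 46 splits gave 8 or more and the highest other gave 13. By single lists, a camera p as small came from 1 split for mitochondrial DNA and for the hypoxia-inducible, calcium and volume regulation list. It came from 2 for glycolysis, 4 for keratinocyte markers, 6 for macrophage markers and 9 each for interferon and autophagy genes. For labelled sex, with 0 calls, the comparison is empty, as any split gives as many (100 of 100). The highest other split, WT 1, WT 2, WT 4 and WT 5 with Opa1cKO 3 and Opa1cKO 6 against the rest, gave 406 calls, and what it reflects was not tested.

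Genes within 10 Mb of Opa1 were called at 13.3% (20 of 150; odds ratio 1.35, 95% interval 0.799 to 2.19, Fisher's exact p = 0.221) and those near Acan at 11.5% (11 of 96; odds ratio 1.14, p = 0.615), so carry-over of strain DNA around either locus cannot be told apart from none.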
